A study of Homo sapiens with 6 samples.

How the data were processed

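Total RNA was measured on 6 arrays from 3 established human cell lines of uveal melanoma: Mel 270, Mel 290 and 92.1. Each line was grown alone and with activated T cells, which gave 3 arrays per group. Per the labels' protocols, 80000 cells of 92.1 and 100000 cells of Mel 270 or Mel 290 were plated, medium was changed to a serum-free one once Mel 290 was confluent and the others nearly so, and culture then lasted 64 h. T cells from the blood of healthy volunteers, activated with beads against CD3 and CD28, sat in inserts with 0.4 µm pores above the melanoma cells. No melanoma cells with resting T cells were among the arrays, and the donors behind each co-culture are not given. Melanoma cells were scraped off for RNA, so the T cells themselves were not part of the sample by design.

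The deposited values are on a log2 scale, as their range from 1.49 to 13.9 shows. Affymetrix Expression Console 1.2.0.20 made them, per the submitters' processing notes. The background correction, the summarization of probes and the normalization are not given in the sources used here. The arrays had nearly the same distribution, with medians from 6.63 to 6.69 and a gap of at most 0.15 between sorted columns over the inner 98% of values, so they were used as deposited. The number of arrays limits the precision, and for low signals so does the background.

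The value table had 33297 probe sets. The array annotation used here listed 21214 of them, 19460 with 1 gene symbol and 1754 with several. The other 12083 stay unnamed here. Only probe sets with 1 symbol were named. Of these, 19429 matched a current symbol in a RefSeq gene table of assembly GRCh38.p14, used for names alone, and 31 kept the annotation's symbol. They stood for 18417 genes. Where a gene had several probe sets the one with the highest mean over the 6 arrays was kept, which concerned 647 of the tested genes. Genes were tested if the mean of their probe set was at or above the 25th percentile, a log2 value of 5.80, which left 13808 genes. The percentile had been planned over probe sets that are not controls, but control probe sets are not marked in the table, so it was taken over the listed ones. Paralogs such as HLA, GBP, IFIT and APOL genes can bind each other's probes, so single members of these families are uncertain. List members without a probe set of 1 symbol were not analysed here.

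The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Co-culture was compared with growth alone using limma 3.58.1 in R 4.3.3, with lmFit and eBayes on log2 values and cell line as a block, because each line was present in both groups. That left 2 residual degrees of freedom, to which the moderated variance added a prior worth 3.10. P-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05 and no fold threshold. The replicates are 3 cell lines with 1 array per line and condition, so p-values measure the spread between lines and not between repeat cultures. An exact two-sided permutation test within 3 pairs could not go below p = 0.25. In the text, a change is the log2 value in co-culture minus that alone, given as the mean ± SD over the 3 lines.

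There were 27 gene lists: chemokines, monocyte-attracting chemokines, CXCR3 and CXCR2 ligands, interferon-gamma response, type I interferon response, MHC class I presentation, MHC class II presentation, TNF and NF-kappaB targets, cytokines and growth factors, complement, immune checkpoint and co-stimulation, death receptor and caspase, cell cycle, cholesterol synthesis, hypoxia and glycolysis, unfolded protein response, immediate early genes, melanocyte differentiation, genes higher in class 1 or in class 2 uveal melanoma, mesenchymal and matrix, and markers of T cells, monocytes and macrophages, B cells, endothelium, retinal pigment epithelium and epithelium. Some genes stand in several lists. Lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, against all other tested genes, and adjusted over the 27 lists. They were tested again with an estimated correlation and with fry. With an estimated correlation camera also uses only the 2 residual degrees of freedom, so it can call little whatever the correlation. A call lost there does not by itself show that correlation between genes made the call. Each line's response rested on 1 array per condition, so it was described without a test by the number of genes at least 2-fold apart and by each list's median, placed among 10000 random lists of the same size drawn within 10 bins of mean expression. Lines were compared in the same limma fit, each minus the mean of the other 2. The spread left after line and culture holds the unequal responses of the lines, and no line had repeat cultures. The SE and p-values of these contrasts therefore do not measure the spread between repeat cultures of a line.

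The text names, for co-culture, up to 15 of the largest rises and up to 10 of the largest falls past the threshold with the same direction in 3 lines, the chemokines past it, and up to 4 members of each list with the largest mean change, or for markers of other cell types the 4 highest by level. For each line it names the 5 largest rises and 3 largest falls among the tested genes, and for the spread between lines the 6 genes with the widest range. For the contrasts between lines it names the 5 largest differences each way and members of the melanocyte and mesenchymal lists. Genes named only to complete a count of 5 or fewer, and those that the text marks so, were chosen after their values were seen.

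On simulated log2 values for the same 13808 genes, with 200 genes changed, the co-culture fit recovered 23.9% of genes changed by 1, 85.1% of those changed by 2 and 100% of those changed by 4 on the log2 scale, with 5 false calls. Each simulated change was the same in all 3 lines apart from noise. Real changes could differ more between lines, and CCL5 (5.35 ± 2.12) and C1S (5.14 ± 2.60) were not called. The recovered shares therefore do not hold for genes whose change varies between lines. In a simulated set of 27 lists with 1 list shifted by 1, camera with the preset correlation called that list and no other. With an estimated correlation its adjusted p was 0.134, so the estimated version missed a true shift of that size in this single run of 6 arrays. The simulated genes varied independently, whereas correlations estimated for the real lists reached 0.50 for cell cycle and 0.95 for cholesterol synthesis. The run therefore cannot show how often the preset correlation calls such lists falsely.

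Alternatives were a fit without the cell line block, leaving out each line in turn, quantile normalization again, cyclic loess, no filter and a filter at the median, a variance trend and a robust prior in limma, the mean of a gene's probe sets, every probe set on its own, an added 2-fold threshold, and fold limits of 1.5 and 3 for single lines. Other pseudocounts had been planned for linear values and were not run because the values were on a log2 scale.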

Results

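Gene expression was measured on 6 arrays of 3 human uveal melanoma lines, Mel 270, Mel 290 and 92.1. Uveal melanoma arises from melanocytes of the eye. Each line was cultured alone or below a porous insert that held activated T cells, so that soluble factors could pass. There was 1 array per line and condition, and the 3 lines served as replicates. Arrays of the same line correlated at r = 0.943 to 0.967 across probe sets, and genes within an array are not independent replicates. The array of 92.1 and that of Mel 270, both grown alone, also correlated at r = 0.943.

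The first comparison asked how the factors of activated T cells changed the melanoma cells, with chemokine genes at its centre. The CXCR3 ligands CXCL10, CXCL11 and CXCL9, which attract activated T cells, were among the largest rises. CXCL10 (probe set 8101126) rose by 9.11 ± 0.83 on the log2 scale (SD, n = 3 lines, 554-fold), from 3.72 to 12.83. CXCL11 rose by 7.44 ± 0.68 and CXCL9 by 6.51 ± 1.06. These 3 lay below the filter level of 5.80 on all 3 arrays grown alone, so their sizes are imprecise: with low values raised to 5.80 they were 131-fold, 53.4-fold and 38.0-fold higher. CXCL8, a neutrophil attractant, rose by 5.49 ± 0.28 (44.8-fold), and CCL2, which attracts monocytes, rose by 4.68 ± 0.67 (25.5-fold). Adjusted p in limma was 0.0034 for CXCL10 and CXCL11, 0.0090 for CXCL9, 0.0029 for CXCL8 and 0.0083 for CCL2, and each was higher in 3 of 3 lines.

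**Figure D1:**
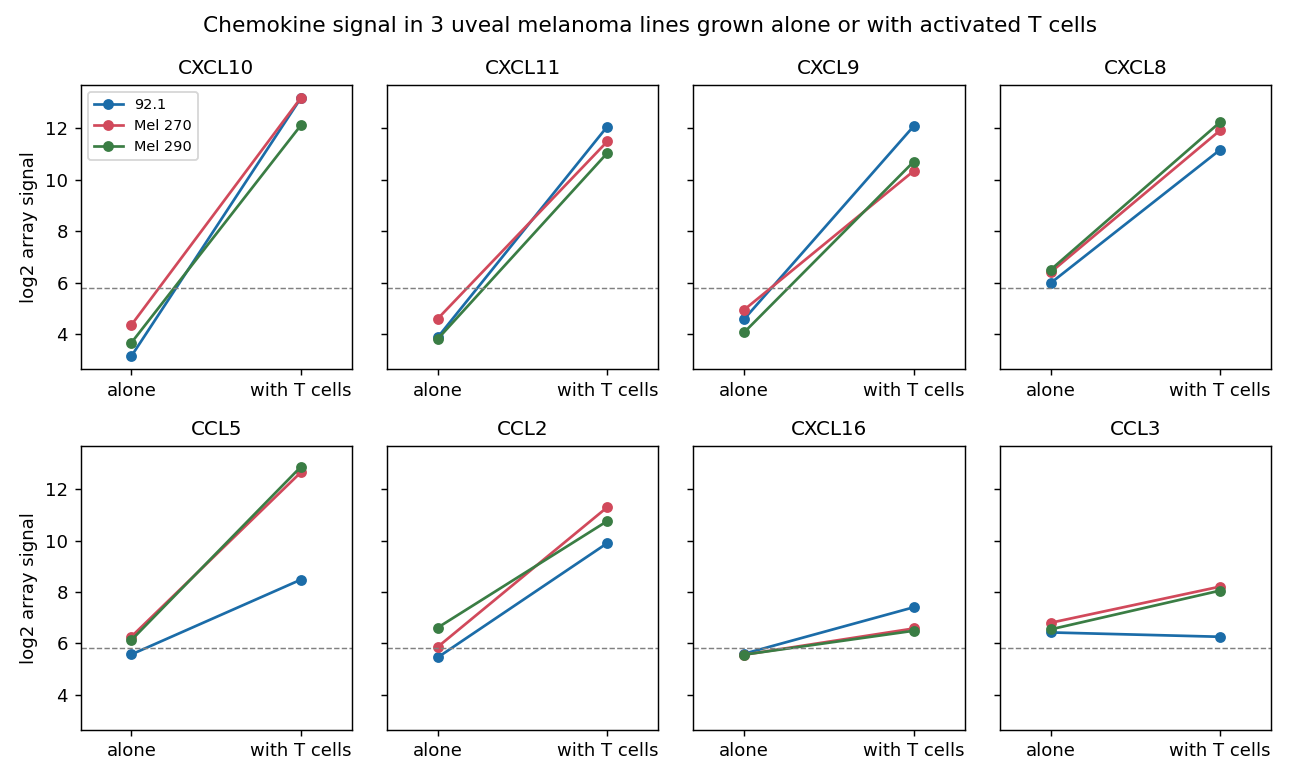
Log2 array signal (vertical axis) of the 8 chemokines with the largest mean change among those above the filter, in each line grown alone or with T cells; points are single arrays, lines join the arrays of a cell line and the dashed line marks the filter at 5.80. CXCL10 went from 3.72 to 12.83 on average, while CCL5 was 2.91 higher in 92.1 and 6.39 and 6.74 higher in Mel 270 and Mel 290.

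Of 16 tested chemokines, 5 rose over all genes and 8 rose when adjusted over the list alone, with none lower (list mean 2.65, camera adjusted p = 8.1e-12, adjusted p = 0.15 with an estimated correlation). CCL5 differed by 5.35 ± 2.12 but did not pass (adjusted p = 0.070), with 2.91 in 92.1, 6.39 in Mel 270 and 6.74 in Mel 290. CXCL1 (0.13 ± 0.16) and CXCL5 (0.17 ± 0.09), ligands of CXCR2 like CXCL8, did not pass, and these 2 were named after their values were seen. Among 7 CXCR3 and CXCR2 ligands 4 rose, and 5 adjusted over the list alone with CXCL3 (0.65 ± 0.41) (mean 4.21, adjusted p = 4.5e-10, adjusted p = 0.15 with an estimated correlation). Among 4 monocyte-attracting chemokines CCL2 alone rose, and CCL2 and CCL5 did when adjusted over the list alone. The mean of this list was 2.86 (adjusted p = 6.3e-05, adjusted p = 0.26 with an estimated correlation), and CCL3 (0.92 ± 0.94) and CX3CL1 (0.50 ± 0.59) did not pass. The monocyte attractants CCL7 and CCL8 and the CCR6 ligand CCL20 lay below the filter on low values and were also chosen after their values were seen. CCL7 was 4.63 higher in Mel 290 and 0.07 and -0.06 apart in the other lines, CCL8 was 4.58 higher in Mel 290, 3.43 higher in Mel 270 and 0.33 lower in 92.1 (difference -0.33), and CCL20 was 0.49, 3.46 and 2.16 higher in 92.1, Mel 270 and Mel 290.

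Interferon-induced genes made up most of the other large rises. IDO1, which degrades tryptophan, rose by 7.51 ± 0.55 (182-fold). The interferon-inducible GTPases GBP5, GBP2 and GBP4 rose by 6.52 ± 1.08, 6.25 ± 1.25 and 5.26 ± 0.86. They too lay below 5.80 on all 3 arrays alone, and with low values raised IDO1 was 54.5-fold, GBP5 38.7-fold, GBP2 43.8-fold and GBP4 15.4-fold higher. The ubiquitin-like modifier UBD rose by 5.31 ± 1.46, and with low values raised it differed by 4.93 (adjusted p = 0.053). Of 20 tested members of the interferon-gamma list 10 rose, and all 20 when adjusted over the list alone (mean 3.52, adjusted p = 7.1e-27, adjusted p = 0.15 with an estimated correlation). In the type I interferon list 13 of 26 rose, and 24 adjusted over the list alone, led by IFI44L (5.72 ± 0.86), IFITM1 (5.51 ± 0.73), BST2 (5.19 ± 0.83) and IFIT2 (4.84 ± 1.30). The mean of that list was 2.88 (adjusted p = 4.0e-31, adjusted p = 0.15 with an estimated correlation). With low values raised to 5.80, IFI44L was 33.1-fold higher (52.7-fold before), BST2 20.5-fold (36.5-fold) and IFIT2 19.2-fold (28.6-fold). IFITM1 hardly moved (44.6-fold, from 45.6-fold). ISG15 (0.34 ± 0.40) did not pass even when adjusted over the list alone. Below the filter, MX1 differed by 0.25 ± 0.75, MX2 by 1.30 ± 1.23 and RSAD2 by 1.71 ± 0.91; these 4 genes were chosen after their values were seen.

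Antigen presentation and checkpoint genes were higher as well. Of 11 MHC class I presentation genes 4 rose, and all 11 when adjusted over the list alone (mean 2.17, adjusted p = 4.9e-15, adjusted p = 0.16 with an estimated correlation). TAP2, a peptide transporter subunit, rose by 2.96 ± 0.74 and the peptide-trimming ERAP2 by 2.39 ± 0.22, next to PSME2 and TAPBP. With low values raised to 5.80, ERAP2 (1.90, adjusted p = 0.094) and PSME2 (1.58, adjusted p = 0.056) were not called. PSME2 had no value below 5.80, so its loss came from the refit over all genes and not from low signal. TAP1 (3.81 ± 1.34) and the immunoproteasome subunit PSMB9 (3.74 ± 1.17) missed the threshold over all genes. Of 8 MHC class II presentation genes only CTSS, a protease that processes the invariant chain, rose (5.38 ± 0.64), and CTSS, HLA-DPA1, HLA-DQA1 and HLA-DMA did when adjusted over the list alone (mean 2.02, adjusted p = 9.2e-07, adjusted p = 0.26 with an estimated correlation). Outside the fixed list HLA-DOB, a class II chain chosen after its value was seen, rose by 2.50 ± 0.64 (adjusted p = 0.045). HLA-DPA1 (3.67 ± 1.18), HLA-DPB1 (2.01 ± 2.11) and HLA-DQA1 (1.83 ± 1.43) did not pass over all genes. Among 11 checkpoint and co-stimulation genes IDO1, CD274 and PDCD1LG2 rose, and 6 adjusted over the list alone (mean 1.72, adjusted p = 2.5e-09, adjusted p = 0.23 with an estimated correlation). CD274, which encodes PD-L1, rose by 4.97 ± 0.59 (31.4-fold), PDCD1LG2, which encodes PD-L2, rose by 2.54 ± 0.09, and CD47 was 1.11 ± 0.21 higher without passing. With low values raised to 5.80 PDCD1LG2 was not called (2.12, adjusted p = 0.068), and CD274 was 20.9-fold higher.

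TNF and NF-kappaB targets, complement and death receptor genes followed the same direction. IL32 (4.16 ± 0.62) and the feedback inhibitor TNFAIP3 (4.09 ± 1.01) were the 2 of 20 NF-kappaB targets that rose, and 17 rose when adjusted over the list alone (mean 2.34, adjusted p = 5.7e-19, adjusted p = 0.15 with an estimated correlation). TNFAIP6 (4.69 ± 2.03) and SOD2 (3.42 ± 1.76) did not pass over all genes. None of 10 complement genes passed over all genes and 7 rose when adjusted over the list alone (mean 2.27, adjusted p = 2.0e-06, adjusted p = 0.22 with an estimated correlation). C1S differed by 5.14 ± 2.60, C3 by 4.19 ± 3.15, C1R by 4.04 ± 2.00 and CFB by 3.24 ± 1.97. PMAIP1 (3.10 ± 0.63), CASP1 (2.78 ± 0.70), the death receptor FAS (1.66 ± 0.19) and CFLAR (1.37 ± 0.24) were the 4 of 12 death receptor and caspase genes that rose, with 7 adjusted over the list alone (mean 1.12, adjusted p = 5.8e-07, adjusted p = 0.15 with an estimated correlation). With low values raised to 5.80 CASP1 (1.62, adjusted p = 0.062) and CFLAR (1.37, adjusted p = 0.053) were not called. CFLAR had no value below 5.80, so its loss came from the refit over all genes and not from low signal. CASP4, the precursor of an inflammatory caspase, differed by 2.40 ± 1.19 without passing over all genes. CFLAR encodes an inhibitor of death receptor signalling, and PMAIP1 encodes the pro-apoptotic NOXA. Another CFLAR probe set, with a mean level of 7.68 against 8.09 for the one used, had a mean change of 0.66.

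Of 14 cytokines and growth factors CSF1, the macrophage growth factor, alone rose (1.70 ± 0.24), whereas IL6 (3.00 ± 2.41), TNFSF13B (1.69 ± 0.43) and IL1B (1.18 ± 2.24) did not pass. Adjusted over the list alone CSF1 and TNFSF13B rose and FGF2 fell (mean 0.67, adjusted p = 0.0014, adjusted p = 0.22 with an estimated correlation). With a filter at the median this list was no longer called (adjusted p = 0.13). No immediate early gene passed over all genes, and adjusted over the list alone ZFP36 (1.79 ± 0.79), JUNB (1.73 ± 0.56), JUN (1.64 ± 0.46) and ATF3 (1.56 ± 0.79) rose and MYC fell (by 0.96 ± 0.27), out of 10 (mean 0.78, adjusted p = 2.0e-04, adjusted p = 0.26 with an estimated correlation). In the unfolded protein response list ATF3, shared with the former list, was the 1 of 13 genes past the threshold adjusted over the list alone and none passed over all genes (mean 0.44, adjusted p = 0.0017, adjusted p = 0.37 with an estimated correlation). DNAJB9 (0.85 ± 1.04), ATF4 (0.69 ± 0.49) and CHAC1 (0.61 ± 1.42) were its next members, and without 92.1 the list was not called (adjusted p = 0.32).

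Proliferation genes were lower in co-culture. None of 26 cell cycle genes passed over all genes, and 24 fell when adjusted over the list alone (mean -1.09, adjusted p = 5.3e-13, adjusted p = 0.29 with an estimated correlation). CDK1 (-1.79 ± 1.22), TYMS (-1.61 ± 0.68), BUB1B (-1.61 ± 0.97) and CCNA2 (-1.58 ± 0.48) differed most, each lower in 3 of 3 lines. Of 16 melanocyte differentiation genes none passed over all genes and SLC45A2 alone fell when adjusted over the list alone (mean -0.67, adjusted p = 9.3e-04, adjusted p = 0.46 with an estimated correlation). SLC45A2 (-1.66 ± 0.74), TYR (-1.27 ± 1.01), SLC24A5 (-1.25 ± 1.19) and MITF (-1.23 ± 0.75) had the largest differences, and without the cell line block the list was not called (adjusted p = 0.20).

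Single genes that fell were few. The potassium channel genes KCNAB2 and KCNH1 fell by 1.65 ± 0.35 and 1.34 ± 0.17, SGO1, a guardian of sister chromatid cohesion, fell by 1.50 ± 0.27, GPD1L fell by 1.30 ± 0.08 and the non-coding gene DLEU1 fell by 1.23 ± 0.11. Their adjusted p lay between 0.036 and 0.046. After cyclic loess GPD1L alone of these 5 was called, and without the cell line block none was. KCNH1 lay below 5.80 in each co-culture, so its fall is imprecise, and with low values raised to 5.80 neither KCNH1 (-0.79, adjusted p = 0.10) nor KCNAB2 (-1.65, adjusted p = 0.053) was called. KCNAB2 had no value below 5.80, so its loss came from the refit over all genes and not from low signal.

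Several lists were not called. Cholesterol synthesis genes had a mean of -0.039 with 0 of 12 past the threshold (adjusted p = 0.83, camera direction up), with STARD4 at 0.47 ± 0.30 and IDI1 at -0.40 ± 0.47. Hypoxia and glycolysis genes had a mean of 0.22 and a median of -0.0062 with 0 of 14 (adjusted p = 0.29), led by ADM (1.49 ± 1.34) and VEGFA (1.06 ± 0.73). Each of these 2 lists hung on single lines: without 92.1 cholesterol synthesis was called higher (0.26, adjusted p = 0.015) and hypoxia higher (0.48, adjusted p = 0.0027), and without Mel 270 cholesterol synthesis was called lower (-0.38, adjusted p = 0.0055). Genes higher in class 2 uveal melanoma, the class with the worse outcome, had 0 of 3 past the threshold (mean 0.17, adjusted p = 0.53), with ECM1 at 0.43 ± 0.83, RAB31 at 0.35 ± 0.39 and HTR2B at -0.25 ± 0.47. Genes higher in class 1 had 0 of 8 over all genes, with EIF1B (0.50 ± 0.09) higher and LTA4H (-0.79 ± 0.20) lower when adjusted over the list alone and ROBO1 (1.01 ± 1.24) past neither (mean 0.011, median -0.15, adjusted p = 0.86). Mesenchymal and matrix genes had 0 of 18 (mean 0.020, median -0.054, adjusted p = 0.83, camera direction down), with FN1 at 1.67 ± 1.38, PDGFRB at -0.55 ± 0.48, TGFBI at -0.47 ± 0.48 and ZEB1 at 0.45 ± 0.68.

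None of the lists of markers of other cell types was called in co-culture. Of 12 tested T cell markers none passed (mean -0.0057, adjusted p = 0.83, camera direction up). The 4 with the highest level were CD7 (0.11 ± 0.03), LTB (-0.16 ± 0.25), NKG7 (0.07 ± 0.33) and the cytotoxic protease gene GZMB (0.22 ± 0.31). CD3D, CD3E and CD3G reached at most 5.70 in the co-cultures, below the filter at 5.80. Monocyte and macrophage markers had 0 of 5 (mean 0.067, median -0.068, adjusted p = 0.83), with CD68 at 0.75 ± 0.63, TYROBP at -0.07 ± 0.20, S100A9 at -0.13 ± 0.31 and CSF1R at -0.28 ± 0.16. B cell markers had 0 of 4 (mean -0.065, adjusted p = 0.83), with CD79B at -0.07 ± 0.03, PAX5 at -0.06 ± 0.20, CD79A at -0.10 ± 0.10 and BLK at -0.04 ± 0.08. The single endothelial marker above the filter, EMCN, had a mean of -1.20 ± 2.24 (camera adjusted p = 0.67). Retinal pigment epithelium markers had 0 of 2 over all genes, with LRAT (-0.65 ± 0.20) lower adjusted over the list alone and BEST1 at 0.58 ± 0.63 (mean -0.035, adjusted p = 0.83). Epithelial markers had 0 of 4 (mean -0.19, adjusted p = 0.83), with KRT18 at -0.20 ± 0.81, KRT8 at -0.65 ± 0.49, KRT7 at 0.06 ± 0.32 and KRT19 at 0.03 ± 0.12.

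In total, 62 of 13808 genes passed an adjusted p of 0.05 in limma, 57 higher and 5 lower, and all 62 had the same direction in 3 lines and at least a 2-fold mean change. At an unadjusted p under 0.05 there were 970 higher and 1791 lower. Camera with the preset correlation called 14 lists higher and 2 lower, 0 with an estimated correlation and fry called 8. The estimated version uses only the 2 residual degrees of freedom, which alone can remove a call. Death receptor and cytokine genes had estimated correlations of -0.034 and -0.014, below the preset 0.01, and were still not called by it. Without 92.1 the fit gave 47 higher and 2 lower genes, without Mel 270 76 and 9, and without Mel 290 72 and 5, and without the cell line block 18 and 0. Of the called genes, 16 lay below the filter level on all 3 arrays grown alone, where signal is mostly background, so their fold changes are imprecise. With low values raised to 5.80, a check chosen after seeing the data here and above, 46 of the 62 genes were still called. The lost calls were mostly of genes other than those below the filter level alone. CFLAR, PSME2, KCNAB2, DDX60 and IFIT5 had no value below 5.80 and kept their mean change, so their loss came from the refit over all genes.

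The second comparison set the response of each line side by side, with 1 array per condition and so no replicate check within a line. CXCL10 differed by 10.04 in 92.1, 8.84 in Mel 270 and 8.46 in Mel 290, against levels alone below the filter at 5.80, so these sizes and the order of such genes are imprecise. In 92.1 the next values were those of ZP4, an egg coat glycoprotein gene, at 8.32, CXCL11 (8.20), IDO1 (8.14) and GBP2 (7.58). In Mel 270 they were those of the complement gene C3 (7.60), IDO1 (7.27), FDCSP (7.07) and CXCL11 (6.90), and in Mel 290 those of CXCL11 (7.23), GBP5 (7.14), IDO1 (7.12) and TNFAIP6 (7.03). The lowest values were those of PKIA (-3.39), MTARC1 (-3.34) and STK32A (-3.19) in 92.1, of LRRC39 (-4.54), TEX15 (-3.95) and EMCN (-3.76) in Mel 270, and of RGS4 (-4.05), GASK1B (-3.80) and CD36 (-3.30) in Mel 290.

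**Figure D2:**
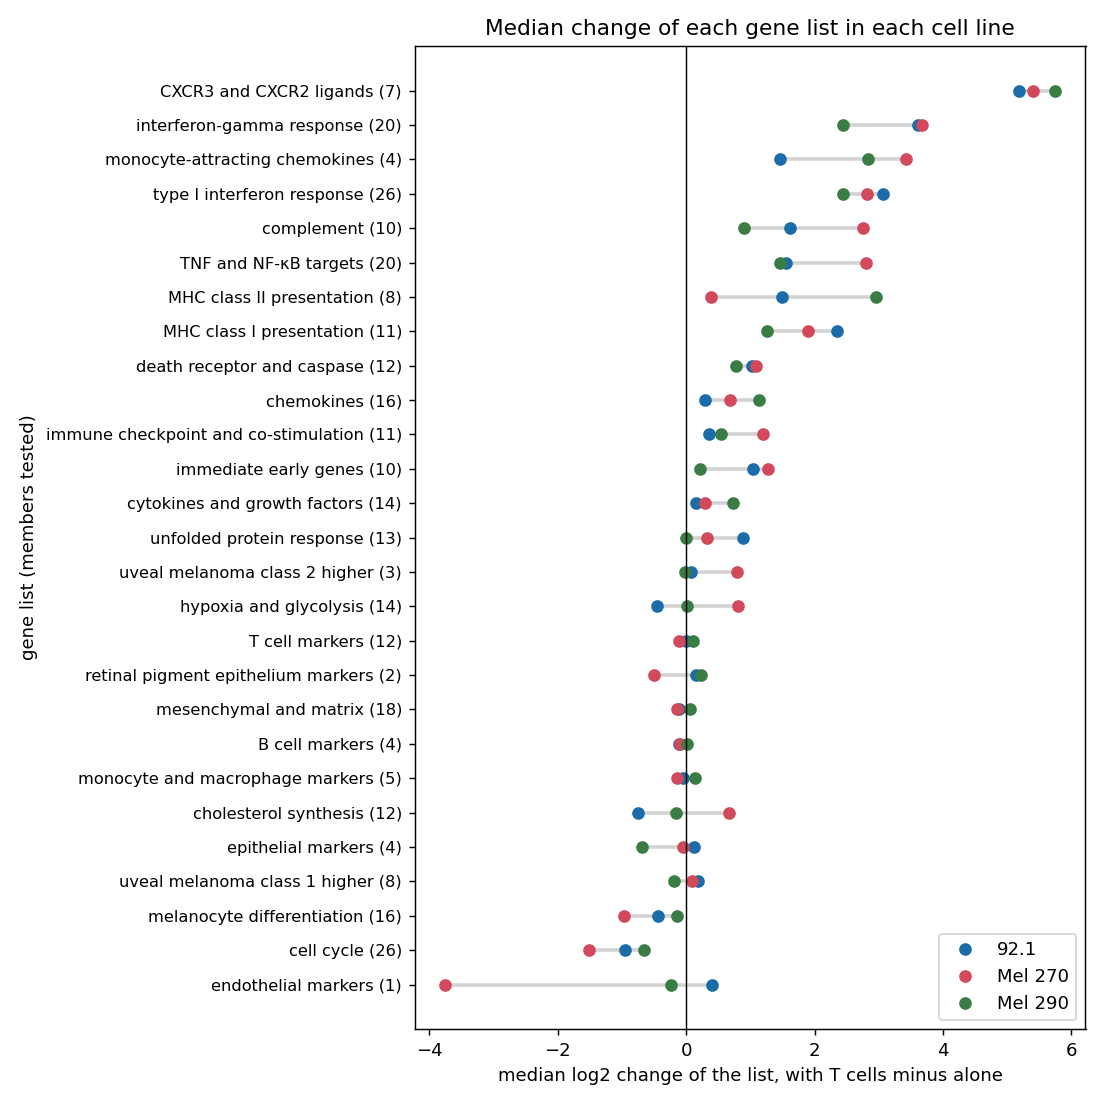
Median log2 change of each gene list, co-culture minus alone (horizontal axis), for the lists with their number of tested members (vertical axis); each point is 1 cell line and the grey bar spans the 3 lines. Interferon-gamma response medians were 3.61, 3.67 and 2.44 in 92.1, Mel 270 and Mel 290, and cell cycle medians were -0.95, -1.52 and -0.66.

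Gene groups differed in size between lines. The interferon-gamma list had medians of 3.61 in 92.1, 3.67 in Mel 270 and 2.44 in Mel 290, and the type I interferon list 3.06, 2.82 and 2.45, each at percentile 100 of the random lists. MHC class II presentation had medians of 1.50, 0.39 and 2.95, with HLA-DPB1 at 1.65 in 92.1, 0.10 in Mel 270 and 4.28 in Mel 290. The cell cycle list had medians of -0.95, -1.52 and -0.66 and lay at percentile 0 of random lists in each line. The melanocyte list had medians of -0.43, -0.97 and -0.14 at percentiles 0.13, 0 and 23.2. In Mel 290 grown alone TYRP1, MLANA, TYR, KIT, EDNRB, PAX3 and SLC24A5 of this list already lay below 5.80 and had little room to fall, so its median there says little about the response. Genes with the widest range over the lines were ZP4 (8.32, -0.25 and 0.59 in 92.1, Mel 270 and Mel 290), SAA2 (-0.55, 6.76 and 3.88), SPP1 (0.25, 4.11 and -2.45), C3 (3.57, 7.60 and 1.39), DDX60L (2.56, -3.08 and 1.36) and LCN2 (-0.24, 5.33 and 0.67).

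At least 2-fold differences were seen in 92.1 for 501 genes higher and 374 lower, in Mel 270 for 730 and 624, and in Mel 290 for 286 and 317. All 3 lines shared 124 higher and 32 lower genes, where independent lists would share 0.55 and 0.39. Across genes the changes correlated at Pearson r = 0.637 between 92.1 and Mel 270 (Spearman rho 0.521), 0.502 between 92.1 and Mel 290 (rho 0.319) and 0.497 between Mel 270 and Mel 290 (rho 0.313), and 0.568, 0.370 and 0.398 without the 62 called genes. These values are over 13808 genes, which are not independent replicates. Of all genes, 41.7% had the same sign in 3 lines, where chance alone gives 25%.

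The third comparison described how the lines differed from each other over both culture conditions. Mel 290 stood apart by low pigment genes. TYRP1, a melanin synthesis enzyme, averaged 5.11 in Mel 290 against 13.13 in 92.1 and 12.85 in Mel 270, a difference of -7.89 (limma SE 0.14, adjusted p = 3.3e-04). MLANA (-6.97), PMEL (-6.52), A2M (-7.17) and the ectonucleotidase gene ENTPD1 (-6.67) were also lower in Mel 290, and TM4SF1 (7.85), DPP4 (6.78), FAP (6.24), ARHGAP29 (6.23) and IL7R (6.21) were higher. Of 16 melanocyte genes 13 were lower in Mel 290 and 1, RAB27A, was higher, or 14 and 1 adjusted over the list alone (adjusted p = 8.9e-08, adjusted p = 0.88 with an estimated correlation). Of 18 mesenchymal and matrix genes 8 were higher, among them CDH2 (4.89) and AXL (4.43), and SNAI2 (-4.17) was lower, or 9 and 1 adjusted over the list alone (adjusted p = 5.3e-05, adjusted p = 0.81 with an estimated correlation).

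**Figure D3:**
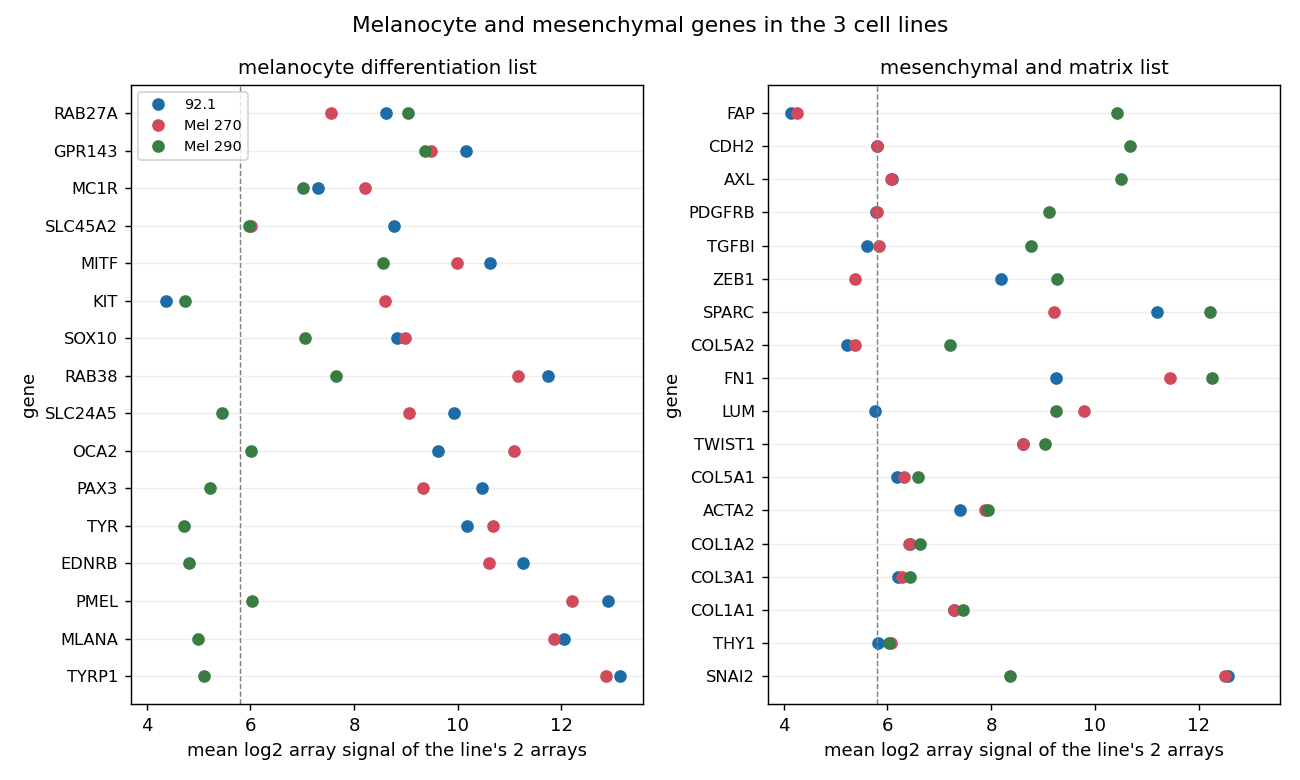
Mean log2 array signal (horizontal axis) of the 2 arrays of each line, alone and with T cells, for the tested melanocyte and mesenchymal genes (vertical axes); points are line means and the dashed line marks the filter at 5.80. TYRP1 lies at 5.11 in Mel 290 and at 13.13 and 12.85 in 92.1 and Mel 270.

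In 92.1, PCDH20 (6.78 above the mean of the other lines), MAL2 (4.97), QPCT (4.68), SLC38A1 (4.65) and HSPA2 (4.59) were highest, and FAM114A1 (-5.53), DPP4 (-4.89), CD109 (-4.85), CRYAB (-4.74) and TM4SF1 (-4.44) lowest. Cell cycle genes were higher in 92.1, 4 of 26 over all genes and 7 adjusted over the list alone (adjusted p = 1.3e-05, adjusted p = 0.79 with an estimated correlation). In Mel 270, HTATIP2 (5.07), PRAME (5.01), a cancer testis antigen, S100A10 (4.98), RELN (4.95) and SLC1A4 (4.88) were highest, and the amino acid transporter SLC38A1 (-7.38), MGST1 (-6.89), FZD6 (-5.85), PLOD2 (-5.62) and ZNF667-AS1 (-5.49) lowest. Cell cycle genes were lower in Mel 270, 6 of 26 over all genes and 10 adjusted over the list alone (adjusted p = 2.0e-05, adjusted p = 0.76 with an estimated correlation). This list also fell most in Mel 270 in co-culture (median -1.52, against -0.95 in 92.1 and -0.66 in Mel 290). The contrast pools both conditions, so part of the lower level in Mel 270 is that response. These differences had adjusted p at or below 0.030 in limma, the largest being that of DPP4 in 92.1.

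Further lists were called in the contrasts. Each contrast is against the mean of the other 2 lines, so melanocyte, mesenchymal and cytokine calls in 92.1 and Mel 270 largely mirror those of Mel 290. They do not by themselves tell 92.1 from Mel 270. Melanocyte genes were higher in 92.1, 10 of 16 over all genes (13 higher and 1 lower adjusted over the list alone, adjusted p = 3.6e-06, adjusted p = 0.79 with an estimated correlation), and in Mel 270, 10 higher and 2 lower (12 and 2 adjusted over the list alone, adjusted p = 1.1e-04, adjusted p = 0.76 with an estimated correlation). Mesenchymal and matrix genes had 1 higher and 8 lower in 92.1 (adjusted p = 0.0031, adjusted p = 0.79 with an estimated correlation) and 1 and 8 in Mel 270 (adjusted p = 0.019, adjusted p = 0.76 with an estimated correlation), the same counts as adjusted over the list alone. Cytokines and growth factors had 6 higher and 1 lower of 14 in Mel 290, over all genes and adjusted over the list alone (adjusted p = 0.0022, adjusted p = 0.81 with an estimated correlation). The same list had 5 lower in 92.1 (adjusted p = 0.0080, adjusted p = 0.79 with an estimated correlation) and 4 lower in Mel 270 (adjusted p = 0.049, adjusted p = 0.76 with an estimated correlation). Cholesterol synthesis genes were higher in Mel 290, 5 of 12, or 6 adjusted over the list alone (adjusted p = 0.011, adjusted p = 0.89 with an estimated correlation). Hypoxia and glycolysis genes had 2 of 14 lower in 92.1, or 5 adjusted over the list alone (adjusted p = 0.0031, adjusted p = 0.83 with an estimated correlation), and in Mel 270 3 higher and 1 lower, or 7 and 1 adjusted over the list alone (adjusted p = 0.036, adjusted p = 0.76 with an estimated correlation). The co-culture medians of this list, -0.45 in 92.1 and 0.81 in Mel 270, enter these 2 contrasts as well. Neither class list of uveal melanoma was called in any line, with adjusted p of 0.34 or more.

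Counts of genes past the threshold were 1344 higher and 853 lower in 92.1, 943 and 1052 in Mel 270, and 1562 and 2053 in Mel 290, each against the mean of the other 2 lines. The 3 contrasts share the same 6 arrays, so a gene low in 1 line counts as high in the others, and each line had 2 arrays of different culture conditions. Where a line lies below 5.80, as Mel 290 does for TYRP1, MLANA, A2M and ENTPD1, the size and order of the differences are imprecise.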

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

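The tests on ZP4 below were chosen only after the result was seen. A few genes changed in opposite directions in different lines, each by at least 2-fold in both directions; with 1 array per line and condition these differences between lines were not tested. Over all tested genes, 15 were at least 2-fold opposite between 92.1 and Mel 270, 13 between 92.1 and Mel 290 and 11 between Mel 270 and Mel 290; the following are those among the members of the gene lists and the genes named per line. SPP1, which encodes osteopontin, had the widest range, 6.56 on the log2 scale, with 4.11 in Mel 270 and -2.45 in Mel 290. The helicase gene DDX60L spanned 5.64, from 2.56 in 92.1 to -3.08 in Mel 270. The matrix gene LUM spanned 4.12, from -1.50 in 92.1 to 2.62 in Mel 290, and the asparagine synthetase gene ASNS spanned 4.10, from 2.61 in 92.1 to -1.49 in Mel 270. ACTA2, a smooth muscle actin, spanned 3.35, from 1.69 in 92.1 to -1.66 in Mel 290. HMGCS1, an enzyme of cholesterol synthesis, spanned 2.35, from -1.30 in 92.1 to 1.05 in Mel 270.

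The cholesterol synthesis list as a whole differed in the same way, with a median of -0.75 in 92.1 (percentile 0 of random lists) and 0.66 in Mel 270 (percentile 99.9), a range of 1.41. The hypoxia and glycolysis list had medians of -0.45 in 92.1 (percentile 0.17) and 0.81 in Mel 270 (percentile 100), a range of 1.26. Neither difference between lines was tested.

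Probe sets that the gene analysis leaves out also carried signal. Of the 1754 probe sets listed with several genes, 15 were at least 2-fold higher in all 3 lines and 0 lower, with a largest mean rise of 5.88. Of the 12083 probe sets without a listed gene, 18 were at least 2-fold higher in all 3 lines and 1 lower, with a largest mean rise of 3.50. Which transcripts they measure was not analysed here.

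ZP4, an egg coat glycoprotein gene, went from 4.75 to 13.07 in 92.1 but differed by -0.25 in Mel 270 and 0.59 in Mel 290. If its probe set read another strongly induced transcript, a further probe set might show the same rise, but the largest other rise seen in 92.1 and under 1 in both other lines was 4.48, for LRP2. A swapped array was argued against by the correlation of r = 0.958 between the 92.1 arrays, above the 0.925 of the co-culture array with its closest array of another line. A fault of this probe set on the single array and a small share of other RNA stay open, and no biological explanation was tested.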

How the results depend on the processing

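The alternative with low values set to 5.80 was chosen only after the result was seen; the others were fixed before. Against 57 higher and 5 lower genes, no called gene reversed in the 11 alternatives compared gene by gene, each over all 62 except the median filter (51). Quantile normalization gave 59 and 5 (60 of the 62 shared), the robust prior 43 and 5, the mean of probe sets 53 and 5, no filter 52 and 4, single probe sets 55 and 5, a 2-fold threshold 57 and 5, and low values set to 5.80 46 and 4. Without the cell line block there were 18 higher and 0 lower genes in limma (816 at an unadjusted p under 0.05) and 1 list lower, the melanocyte list being lost. Cyclic loess gave 40 higher and 1 lower, the median filter 57 and 9, the variance trend 58 and 9. Leaving out each line gave 2 to 9 lower genes: 47 higher and 2 lower without 92.1, 76 and 9 without Mel 270, 72 and 5 without Mel 290, with 37, 53 and 38 of the 62 shared. Fewer lines enter these fits; for the other shifts the cause was not tested. Lists called were 0 higher and 0 lower with an estimated correlation and 8 and 0 with fry. At 1.5-fold, 92.1 had 1077 higher and 1384 lower genes, Mel 270 1482 and 1571, Mel 290 658 and 1219, and all 3 lines 260 and 293. At 3-fold these were 253 and 60, 348 and 238, 140 and 45, and 67 and 1. Direction reversed in lists not called with all lines. Leaving out each line, list means ranged from -0.38 (without Mel 270, adjusted p = 0.0055) to 0.26 (without 92.1, adjusted p = 0.015) for cholesterol synthesis, -0.16 (without Mel 270) to 0.48 (without 92.1, adjusted p = 0.0027) for hypoxia, -0.11 to 0.11 for class 1 genes, -0.032 to 0.089 for mesenchymal genes, -0.088 to 0.054 for T cell markers, -1.99 to 0.083 for the endothelial marker, -0.17 to 0.20 for retinal pigment epithelium and -0.35 to 0.029 for epithelial markers. Cholesterol synthesis was 0.052 with cyclic loess, B cell markers 0.018 without a filter, retinal pigment epithelium 0.58 with the median filter (1 gene fewer) and T cell markers 0.0057 with the mean of probe sets. Of called lists, unfolded protein response was lost without 92.1 (adjusted p = 0.32) and cytokines with the median filter (adjusted p = 0.13). Over all alternatives of the fit, adjusted p ran from 3.2e-04 to 0.32 for unfolded protein response, 7.4e-06 to 0.13 for cytokines, 9.9e-05 to 0.20 for melanocyte genes, 0.0055 to 0.97 for cholesterol synthesis and 0.0027 to 0.39 for hypoxia. Counts between lines stayed within 1.5 times. Correlations were judged by a fixed limit on their shift, without an SD, and stayed within it. Other pseudocounts were not run. Arrays limit low signals: 16 called genes lay under 5.80 on all 3 arrays grown alone.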

Other observations

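The T cell RNA test, the normalization test on cell cycle genes, the tests on MHC class II genes and the gene families below were chosen only after the result was seen. The real split of the 6 arrays called 62 genes, and the highest of the other splits called 0; 1 of 10 splits called as many. Over the gene lists the real split called 16 lists and the highest other called 17, so that 3 of 10 splits called as many. With 10 splits no share under 0.05 can be had. The 2 splits with 17 lists part only 1 pair of arrays. With cell line as a block, the coefficient of such a split is the co-culture change of that 1 line. The 3 others that part all 3 pairs called 0 genes and 8 to 10 lists, and they turn the sign of the change in 1 line. No other split was thus free of the co-culture response. In each of them that response adds to the residual spread, so strong changes shared by all lines would themselves give 0 called genes. Neither count can therefore tell whether the calls arose by chance, nor how often camera calls lists falsely.

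RNA from T cells is a possible source of the co-culture signal, although the insert kept them apart. The markers' median change, taken over 25 T cell genes without a filter, was at most 0.133 in any line, the largest rise of a single marker was 0.67, and CD3D, CD3E and CD3G reached at most 5.70 in co-culture. This argues against T cell RNA as the whole cause. At the filter level or above lay 12 of these markers, in melanoma cells grown alone or in co-culture.

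Lower cell cycle genes may reflect fewer dividing melanoma cells in co-culture. A normalization effect or an intensity trend was argued against by a list mean of -1.06 after cyclic loess and by percentile 0 among expression-matched lists in each line. In a test written before its result was seen, 16 centromere protein (CENP) genes outside the list had a median change of -0.67, with 13 lower and medians of -0.76 in 92.1, -0.94 in Mel 270 and -0.36 in Mel 290. These genes are regulated with the cell cycle like the list itself, and lower transcription per cell would give the same values. The CENP values met the written prediction for fewer dividing cells. Other families, looked at later, were mixed. The median was -0.66 over 11 MCM genes, some of them in the list, -0.16 over 37 KIF genes (mean -0.42) and -0.070 over 48 histone genes. Histone genes were made to count in the verdict only after their value was seen. As lower transcription per cell is not excluded, whether fewer cells divided stays open. So does whether T cell factors, shared medium or crowding lay behind it, since there is no arm with resting T cells.

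MHC class II genes differed between lines. HLA-DPA1 was 3.96, 2.37 and 4.67 higher in 92.1, Mel 270 and Mel 290, HLA-DMA 2.28, 0.68 and 2.02, and HLA-DMB 1.35, -0.58 and 2.42, while their regulator CIITA differed by 0.36, -0.05 and 0.62. These differences between lines had no statistical test. The interferon-gamma list median of 3.67 in Mel 270, the highest of the lines, was also looked at, as were HLA-DMA, HLA-DMB and CIITA, for a reason behind the low values in Mel 270. CIITA decided nothing, and no explanation is offered.

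Among gene families by symbol, the metallothioneins, metal-binding proteins, had a mean change of 0.82 over 12 genes (camera adjusted p = 1.6e-06, adjusted p = 0.40 with an estimated correlation), with medians of 0.24, 1.26 and 0.73 in the lines. Ribosomal protein genes had means of -0.27 over 37 RPL and -0.32 over 22 RPS genes (adjusted p = 8.0e-06 and 3.5e-05), and 41 NDUF genes of mitochondrial complex I a mean of -0.31 (adjusted p = 1.9e-06, adjusted p = 0.40 with an estimated correlation for these 3 families). After cyclic loess the means were 0.83 for metallothioneins, -0.18 for RPL, -0.22 for RPS and -0.27 for NDUF, and after quantile normalization 0.81, -0.25, -0.29 and -0.31. The median of all genes was -0.041, or -0.030 after cyclic loess and -0.052 after quantile normalization.

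Beyond the called genes, 67 were at least 2-fold higher and 27 at least 2-fold lower in all 3 lines. Among them IL24, a cytokine gene, differed by 2.77 ± 0.89 (adjusted p = 0.065), NAMPT, an enzyme of NAD synthesis, by 1.59 ± 0.35 (adjusted p = 0.051) and WNT5A by 1.50 ± 0.49 (adjusted p = 0.070). ALDH1B1 differed by -2.12 ± 0.80 (adjusted p = 0.072), PPARGC1A by -1.99 ± 0.71 (adjusted p = 0.070) and ACAT1 by -1.62 ± 0.49 (adjusted p = 0.067). These 6 genes were picked after their values were seen and none passed the threshold. The 27 lower genes also held cell cycle genes outside the fixed list, such as CDKN3 (-1.93 ± 0.97), KIF11 (-1.77 ± 1.03) and DLGAP5 (-1.70 ± 0.76). They were picked in the same way.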
